A study of Medicago truncatula with 6 samples.

How the data were processed

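The study sequenced RNA of Medicago truncatula hairy roots in 6 libraries, 3 with an empty vector and 3 with an inducible RiNLE1 construct. Samples were grouped by their titles, which also give a replicate number. The table of the whole series holds 1 entry per gene. Raw counts per gene were deposited by the authors for each library, from paired reads per the file headers. The authors' RPKM columns scale counts by gene model length and library total. The authors' TPM columns have the same sum in each library, and mean TPM values per group were also deposited. A further signal in the deposited table, headed CPM, is each count multiplied by 1 factor per library, so that its columns sum to between 975403 and 1023992. The aligner, the counting tool, the genome build and the annotation version are not given in the sources used here. Coordinates are those of the table, and descriptions are the authors', some cut off at a comma. No ID of the table matched the reference gene table (0 matches), so names and descriptions come from the table alone. All per-sample columns could be matched to a sample.

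The entry read as the effector was left out of library sizes and gene tests, and reported by itself. Counts of the other genes were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 21100, and libraries were scaled with TMM. Dispersions were estimated with estimateDisp, and a quasi-likelihood F test compared RiNLE1 with EV (glmQLFit with robust estimation, glmQLFTest, two-sided), with Benjamini-Hochberg adjustment. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled, and those of the effector are per plain library total. The common biological coefficient of variation was 0.217 and the median standard error of a log2 fold change 0.178, or 0.134 over the 12833 genes with a mean of at least 10 CPM. Replicates were not duplicates of one library: the chi-square per degree of freedom over genes was between 15.7 and 45.4 for every pair of libraries.

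The named genes follow a rule written before the data were examined. With no gene past the threshold, it takes the 10 genes with the smallest unadjusted p, and it allows any tested gene of the symbiosis and histone H2B lists. A member of another list was to be named only if it passed the test, and none did, so those named were chosen after their values were seen. The rule, the tests, and 40 gene lists defined by words in the descriptions or by locus were written before the data were examined. Lists with at least 5 tested members were tested with camera from limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2. Beside it stand camera with an estimated correlation, and fry. The words of 10 lists also caught unrelated descriptions, or missed truncated ones, and were corrected after the descriptions were seen. Counts of called lists refer to the lists as first fixed.

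Alternatives were other scalings (RLE, upper quartile, none), other count filters (none, a mean of at least 10 counts), DESeq2 1.42.0, limma-voom, the replicate number as a block, and each library left out in turn. Added after seeing the data were edgeR's likelihood ratio and exact tests, a fit without robust estimation, 1 surrogate variable from sva 3.50.0, both libraries numbered 1 left out, DESeq2 with each library left out, and the corrected lists. An adjusted p that DESeq2 gave as missing stayed out of its counts. The tests were run on simulated counts for the 21100 genes with 200 changed. edgeR recovered 33% of genes changed 2-fold and 80% of those changed 4-fold, with 15 false calls among 20900 unchanged genes. DESeq2 recovered 53% and 89%, with 70 false calls. These shares hold for 200 changed genes that vary independently, and with fewer changed genes the adjustment is stricter. The effector entry, at a log2 fold change of 10.32, had an adjusted p of 0.462 in edgeR's quasi-likelihood test. A gene that this test did not call may therefore still differ. In 5 simulations of this comparison with no changed gene, edgeR called between 0 and 2 genes and DESeq2 between 23 and 34.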

Results

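RNA was sequenced from hairy roots of the legume Medicago truncatula, which are roots that grow from tissue transformed with Agrobacterium. The roots carried either a dexamethasone-inducible construct for RiNLE1, an effector protein of an arbuscular mycorrhizal fungus, or the matching empty vector (EV). All roots had received 10 µM dexamethasone for 20 h, so that the groups differed in the construct and not in the inducer. There were 3 libraries in each group, and the labels do not say whether they came from separate transformations or plants. All p-values therefore measure only the spread between these libraries, which may be technical. Totals ran from 17628994 to 18548414 counts per library, with between 25329 and 25521 genes detected in each. Of the 50894 Medicago genes in the table, 22492 had no count in any library and 21100 had enough counts in enough libraries to be tested.

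The question of the design was which root transcripts differ when the effector is expressed, with plant defence genes as the stated interest. The effector sequence was examined first. The table holds 1 entry, RirG128600, without a description and placed on a sequence of its own (positions 1 to 903) outside the Medicago chromosomes, and the number 128 in its name is also in the label of the RiNLE1 construct. It was read as the effector on these grounds and because nearly all of its counts lay in the RiNLE1 libraries. It had 2, 61 and 10 counts in EV replicates 1, 2 and 3, and 50171, 18990 and 27748 counts in RiNLE1 replicates 1, 2 and 3. Scaled by library total, these are 1.34 ± 1.76 CPM (SD, n = 3) in EV and 1765 ± 856 CPM (SD, n = 3) in RiNLE1. In the authors' TPM values it ranked 6, 29 and 12 among all entries of the 3 RiNLE1 libraries. The highest EV library reached 0.325% of the lowest RiNLE1 library. The log2 fold change was 10.32 (SE 1.00), and its edgeR adjusted p was 0.462 when the entry was tested together with all genes. At 3 libraries per group, edgeR's quasi-likelihood test thus did not call even this difference. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1.

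**Figure D1:**
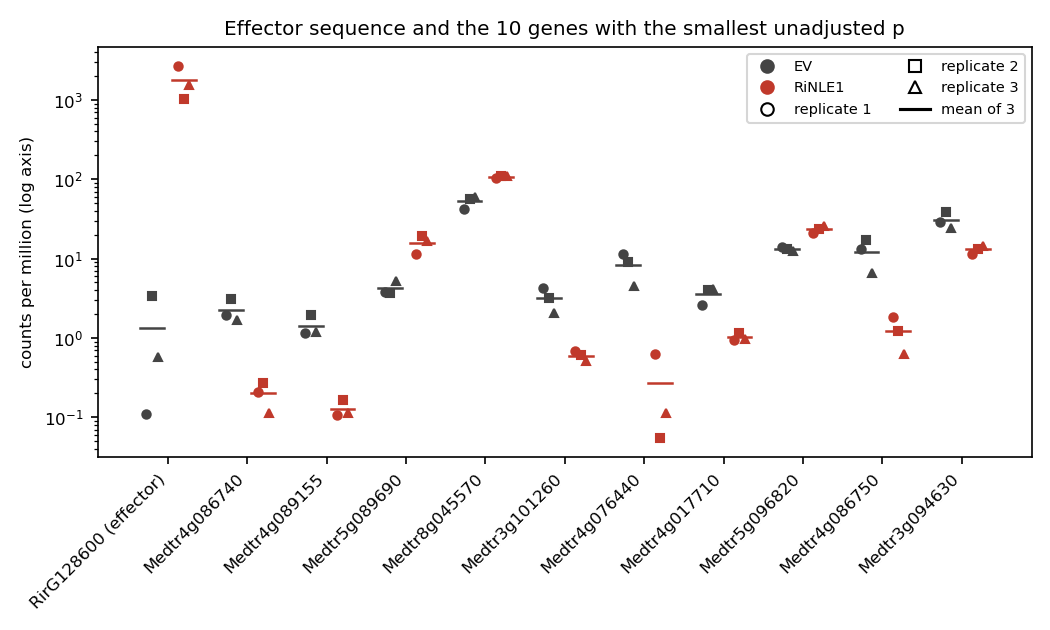
CPM on a log axis for the effector sequence and the 10 Medicago genes with the smallest unadjusted p, with 1 point per library (shape gives the replicate number) and a line at the mean of the 3 libraries of each group. The effector averaged 1765 CPM in RiNLE1 and 1.34 CPM in EV, and for each of the 10 genes the 3 RiNLE1 libraries lay on one side of the 3 EV libraries.

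Among Medicago genes, the 10 with the smallest unadjusted p included a beta-glucan hydrolase, 3 plastocyanin-like proteins and a peroxidase, with lower values in RiNLE1, and a pathogenesis-related protein of the Bet v I family, with higher values. Medtr4g076440, annotated as a glucan endo-hydrolase, averaged 8.35 ± 3.48 CPM in EV and 0.267 ± 0.318 CPM in RiNLE1 (SD, n = 3), a log2 fold change of -4.91 (SE 0.71). The plastocyanin-like genes Medtr4g086740, Medtr4g086750 and Medtr3g101260 had log2 fold changes of -3.44 (SE 0.44), -3.30 (SE 0.49) and -2.39 (SE 0.35). Some proteins with this domain bind copper, and whether these 3 do was not examined. Of all 22 tested plastocyanin-like genes, 12 had estimates below and 10 above 0. Medtr3g094630, a horseradish peroxidase-like protein, averaged 30.5 ± 7.11 CPM in EV and 13.0 ± 1.62 CPM in RiNLE1. Medtr8g045570, of the Bet v I family, averaged 53.2 ± 9.30 CPM in EV and 108 ± 3.38 CPM in RiNLE1, a log2 fold change of 1.02 (SE 0.14).

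None of these genes passed the planned test. edgeR's quasi-likelihood test called 0 of 21100 genes at an adjusted p under 0.05, and 0 with a change of at least 2-fold; the lowest adjusted p was 0.707. At an unadjusted p under 0.05 there were 776 genes, 468 higher and 308 lower in RiNLE1, where 1055 would be expected by chance. limma-voom also called 0 genes. DESeq2 called 41 genes, 25 higher and 16 lower, of which 32 changed at least 2-fold. It gave an adjusted p to 25630 genes, a larger set than edgeR's, and 37 of its 41 calls were among the genes edgeR tested; all 10 genes with the smallest edgeR p were among them. The libraries of the groups did not overlap for 1693 genes, or 8.02% of those tested, against the 10% that chance gives.

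The remaining genes with the smallest edgeR p missed the threshold likewise. Medtr4g089155, a serine carboxypeptidase-like protein, averaged 1.41 ± 0.443 CPM in EV and 0.128 ± 0.0319 CPM in RiNLE1 (SD, n = 3). Medtr4g017710, annotated as verticillium wilt resistance-like, averaged 3.59 ± 0.848 CPM and 1.02 ± 0.111 CPM. Medtr5g089690, a nonsense-mediated mRNA decay protein, averaged 4.23 ± 0.889 CPM in EV and 15.8 ± 3.81 CPM in RiNLE1, with a log2 fold change of 1.90 (SE 0.24). Medtr5g096820, a galactinol-raffinose galactosyltransferase of oligosaccharide metabolism, averaged 13.3 ± 0.783 CPM and 23.4 ± 2.62 CPM. DESeq2 called 7 genes in the fit of all 6 libraries and again in each of the 6 fits that left out 1 library. They were Medtr4g076440, Medtr4g086740, Medtr4g086750, Medtr3g094630, Medtr5g089690, Medtr8g045570 and Medtr2g022490. Medtr2g022490, an extracellular dermal glycoprotein chosen after its values were seen, averaged 37.5 ± 8.40 CPM in EV and 107 ± 27.7 CPM in RiNLE1. Without EV replicate 2, DESeq2 called 12 genes, and without RiNLE1 replicate 1 it called 159.

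Pathogenesis-related genes went both ways. Of 63 tested genes with such descriptions (word patterns corrected after the descriptions were seen), 0 passed edgeR over all genes and 1, Medtr8g045570, passed when adjusted over the list alone (adjusted p = 0.0108). With the patterns as first fixed, 1 of 55 genes passed when adjusted over the list alone. At an unadjusted p under 0.05, 6 were higher and 6 lower in RiNLE1, or 6 and 2 with the patterns as first fixed. camera did not call the list as first fixed (adjusted p = 0.538), but called it higher without EV replicate 2 (adjusted p = 0.0286). The 6 higher genes were all described as of the Bet v I family and lay together on chromosome 8. This stretch, from position 17717066 to 17855266 in the coordinates of the table, held 8 tested Bet v I genes. All 8 had log2 fold changes above 0, from 0.35 to 2.39, with a median of 0.87. Among them Medtr8g045640 averaged 218 ± 55.4 CPM in EV and 318 ± 38.4 CPM in RiNLE1, and Medtr8g045555 averaged 21.9 ± 7.98 CPM and 57.2 ± 34.1 CPM (SD, n = 3). The largest change, 2.39 (SE 0.76), was that of Medtr8g045400, which rested on few reads at 0.300 CPM in EV and 1.60 CPM in RiNLE1. The smallest, 0.35 (SE 0.23), was that of the well-expressed Medtr8g045490, at 360 and 457 CPM. The lower genes included 3 annotated as allergen Pru or as an ABA-responsive protein that DESeq2 called. Membership of the Bet v I family was read from descriptions alone, and was not examined for these 3. Medtr7g102380 had a log2 fold change of -4.12 (SE 0.92), Medtr2g035210 of -2.94 (SE 0.61) and Medtr1g062590 of -1.93 (SE 0.44); DESeq2 called them again in 2, 3 and 3 of the 6 fits with 1 library left out. Genes of the lists named here and below, other than the 10 above and the symbiosis and histone genes, were chosen after their values were seen. Over the 38 tested lists as first fixed, 3 genes in all passed when adjusted over their list alone. Over the 39 tested lists with corrected patterns there were 5. These adjustments took no account of the number of lists, so single passes of this kind may be due to chance. Whether neighbouring copies share reads was not tested, so the values of single family members are uncertain.

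**Figure D2:**
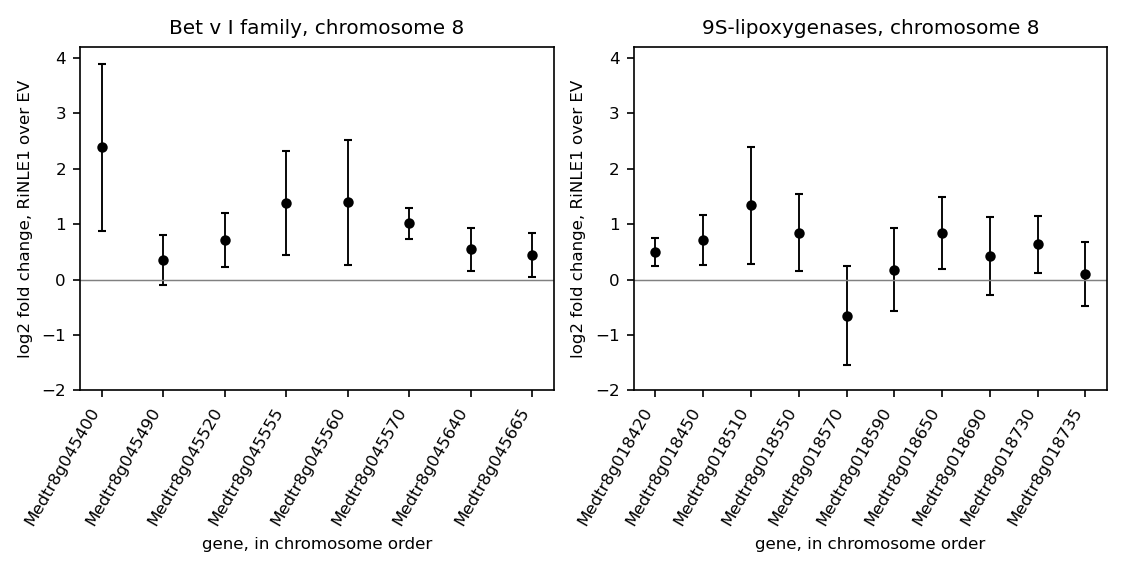
Log2 fold changes (RiNLE1 over EV) of the tested Bet v I family genes and 9S-lipoxygenase genes of chromosome 8 in chromosome order, with points for the edgeR estimate and bars of 2 SE on each side. All 8 Bet v I genes (median 0.87) and 9 of the 10 lipoxygenase genes (median 0.57) had estimates above 0; other splits of the 6 libraries also gave 8 of 8 and 9 of 10, with medians up to 0.41 and 0.566.

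Chitinases and glucan endo-hydrolases, cell wall hydrolases of defence, were not called as a list by camera (adjusted p = 0.121; 0.582 with the patterns as first fixed). Of 49 tested genes (patterns corrected after the descriptions were seen), 20 had estimates above and 29 below 0. None passed over all genes and 1, Medtr4g076440, passed when adjusted over the list alone (adjusted p = 0.0127). The 23 genes of the patterns as first fixed gave 0 such calls (lowest adjusted p = 0.0832), and their median log2 fold change was -0.13, or 0.02 without EV replicate 1. At an unadjusted p under 0.05, 2 of the 49 were higher and 6 lower. Medtr4g076440 (chromosome 4, 29228522 to 29231106) and its neighbour Medtr4g076470 (29237788 to 29241475) had nearly equal counts in each EV library, 208 and 198, 162 and 161, and 81 and 85. In RiNLE1 they had 12 and 30, 1 and 1, and 2 and 11 counts. The pair may share reads. Medtr8g074335, a class Ib chitinase, averaged 187 ± 54.2 CPM in EV and 62.4 ± 38.5 CPM in RiNLE1 (SD, n = 3), and the chitinase Medtr2g040690 averaged 7.01 ± 1.37 CPM and 15.6 ± 6.35 CPM.

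Among oxidative enzymes, 79 class III peroxidase genes (corrected patterns) were tested, and 1, Medtr3g094630, passed when adjusted over the list alone (adjusted p = 0.0294; 0.0309 with the patterns as first fixed), where 0 passed over all genes. At an unadjusted p under 0.05, 2 were higher and 6 lower. camera did not call the list as first fixed (adjusted p = 0.814, median 0.01), but called it lower without EV replicate 1 (adjusted p = 0.0354, median -0.10). DESeq2 also called Medtr3g466180, a cationic peroxidase with a log2 fold change of -1.95 (SE 0.49), and did so again in 2 of the 6 fits with 1 library left out. Medtr2g029910 averaged 109 ± 95.5 CPM in EV and 13.4 ± 8.81 CPM in RiNLE1, with the EV libraries far apart. Respiratory burst oxidases, the enzymes that make superoxide at the plasma membrane, had a median log2 fold change of 0.20 over the 10 genes of the corrected patterns and of 0.04 over the 55 genes of the patterns as first fixed. In both, 0 passed over all genes or when adjusted over the list alone. Medtr1g083290 averaged 52.9 ± 4.97 CPM in EV and 95.8 ± 29.2 CPM in RiNLE1.

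For WRKY transcription factors, which regulate many defence genes, 71 were tested, 33 with estimates above and 38 below 0. None passed over all genes or when adjusted over the list alone; 1 was higher and 3 lower at an unadjusted p under 0.05. The higher one, Medtr2g033820, was called by DESeq2 at 5.91 ± 0.502 CPM in EV and 10.1 ± 0.752 CPM in RiNLE1, but in 0 of the 6 fits with 1 library left out. Medtr7g073430 averaged 37.0 ± 4.52 CPM and 19.8 ± 9.78 CPM. Of 12 terpene synthases, 1 passed when adjusted over the list alone, the sesquiterpene synthase Medtr3g464190 (adjusted p = 0.0448; log2 fold change 1.59, SE 0.37). Another, Medtr6g008560, averaged 31.1 ± 24.0 CPM in EV and 6.55 ± 0.140 CPM in RiNLE1. Intracellular receptors of the nucleotide-binding class had a median log2 fold change of 0.03 over 552 genes, 306 above and 246 below 0, and a mean of -0.01; 0 passed over all genes or when adjusted over the list alone. camera did not call them (adjusted p = 0.418), except without RiNLE1 replicate 2 (adjusted p = 0.0397).

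As whole lists, camera with a preset correlation called receptor-like kinases and ribosomal proteins lower, and protease inhibitors, jasmonate and lipoxygenase genes, photosynthesis genes and nitrate and peptide transporters higher. All 6 calls were lost when the correlation was not preset: for each, the adjusted p was 0.961 with an estimated correlation. In fry, which asks of a list whether it changed at all, each had an adjusted p of 0.994. They were 6 of the 38 lists with enough tested members. Receptor-like kinases, the cell-surface receptors of the plant, had a median log2 fold change of -0.12 over 634 genes, with 442 below and 192 above 0 (adjusted p = 0.00017). Of these, 31 were lower and 6 higher at an unadjusted p under 0.05, and DESeq2 called Medtr4g016850, at 4.41 ± 1.22 CPM in EV and 1.07 ± 0.455 CPM in RiNLE1. It was called again in 2 of the 6 DESeq2 fits with 1 library left out. Ribosomal proteins had a median of -0.11, with 221 of 245 genes below 0. Protease inhibitors, which block digestive enzymes of attackers, had a median of 0.36 with 25 of 33 genes above 0. Among them the Bowman-Birk inhibitor Medtr7g077210 averaged 4.59 ± 1.07 CPM in EV and 11.5 ± 4.27 CPM in RiNLE1. The jasmonate list had a median of 0.19 over 45 genes, or 0.21 over 37 genes once unrelated words were removed. Its members at an unadjusted p under 0.05 were 8 genes, all higher. They were mainly lipoxygenases described as 9S, which act on linoleate outside the jasmonate pathway, such as Medtr8g018730 at 704 ± 180 and 1094 ± 266 CPM. The jasmonate-ZIM-domain gene Medtr8g021380, of a family of jasmonate repressors, averaged 14.5 ± 1.40 CPM in EV and 24.8 ± 4.88 CPM in RiNLE1. Photosynthesis genes had a median of 0.15 with 51 of 66 above 0, and nitrate and peptide transporters a median of 0.09 with 34 of 56 above 0. In none of the 6 lists did a member pass over all genes or when adjusted over the list alone.

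**Figure D3:**
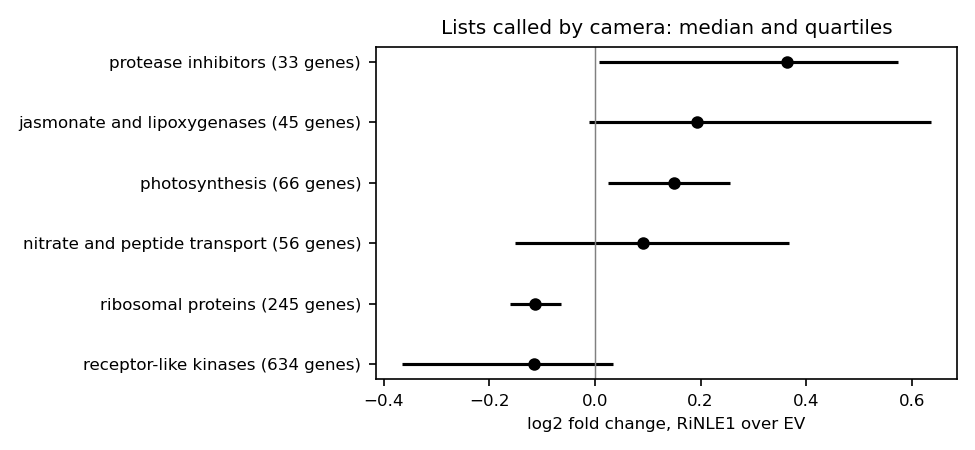
Median (point) and quartiles (line) of the log2 fold changes (RiNLE1 over EV) of the tested members of the 6 lists that camera called with a preset correlation. The medians ran from -0.12 for receptor-like kinases to 0.36 for protease inhibitors, and these were -0.04 without EV replicate 2 and 0.09 without RiNLE1 replicate 3.

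With the correlation between genes estimated from the data, 0 of the 38 lists passed, and fry also called 0. Photosynthesis was the only list of the 6 that camera called in each fit with 1 library left out. The groups still overlapped for this list. Its median deviation from the mean of all libraries was 0.126 in EV replicate 3, above the 0.058 and 0.080 of RiNLE1 replicates 1 and 3. Another split of the 6 libraries gave photosynthesis a larger median log2 fold change, 0.201 against 0.149. Receptor-like kinases lost the call without EV replicate 2 (adjusted p = 0.136, median -0.04), and ribosomal proteins without RiNLE1 replicate 3 (adjusted p = 0.126, median -0.06). In other such fits the medians moved further from 0, to -0.18 for receptor-like kinases without RiNLE1 replicate 3 and -0.19 for ribosomal proteins without EV replicate 2. Protease inhibitors and the jasmonate list lost it without EV replicate 1 (adjusted p = 0.27 and 0.473) and without RiNLE1 replicate 3 (adjusted p = 0.082 and 0.0975). The median of the jasmonate list was 0.01 without EV replicate 1 and 0.09 without RiNLE1 replicate 3. That of protease inhibitors was 0.26 and 0.09 in these fits, and that of photosynthesis genes reached 0.28 without EV replicate 3. Nitrate and peptide transporters kept it in 2 of the 6 such fits. Without EV replicate 1 their adjusted p was 0.632, without EV replicate 3 it was 0.0642, without RiNLE1 replicate 2 it was 0.0908 and without RiNLE1 replicate 3 it was 0.275 with a median of 0.03.

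Symbiosis genes, listed by locus before the data were examined because the effector comes from a symbiotic fungus, had a median log2 fold change of 0.18 over 16 tested loci, 10 above and 6 below 0. None passed over all genes or when adjusted over the list alone. camera did not call the list (adjusted p = 0.168), but called it higher without EV replicate 2 (adjusted p = 0.00279), without RiNLE1 replicate 1 (adjusted p = 0.0417) and without both libraries numbered 1 (adjusted p = 0.0344). The smallest unadjusted p belonged to the GRAS transcription factor Medtr3g072710, at 1.67 ± 0.366 CPM in EV and 3.24 ± 0.630 CPM in RiNLE1 (SD, n = 3), with a log2 fold change of 0.95 (SE 0.27). The calmodulin-domain kinase Medtr8g043970 averaged 58.0 ± 8.09 CPM and 66.0 ± 8.60 CPM, and the ABC transporter Medtr8g107450 averaged 1.11 ± 0.177 CPM and 0.861 ± 0.117 CPM. The glycerol-3-phosphate acyltransferase Medtr1g040500 had 439, 34.6 and 20.5 CPM in EV replicates 1, 2 and 3, and 231, 32.1 and 43.3 CPM in RiNLE1 replicates 1, 2 and 3. Its log2 fold change was -0.69 (SE 1.26), and 1.89 without EV replicate 1. The histone H2B.1-like gene Medtr4g132367 averaged 0.743 ± 0.184 CPM in EV and 0.885 ± 0.342 CPM in RiNLE1. Its log2 fold change was 0.25 (SE 0.39), and -0.08 without RiNLE1 replicate 3.

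EV replicate 1 and RiNLE1 replicate 1 stood apart from the other 4 libraries. The first principal component of log2 CPM held 42.2% of the variance, with EV replicate 1 at -58.2 and RiNLE1 replicate 1 at -27.6, and the others from 7.89 to 34.1. The second held 22.0%, with the EV libraries at 6.32, 34.0 and 17.9 and the RiNLE1 libraries at -11.2, -41.3 and -5.68. On the third, which held 15.7%, the groups overlapped. Chance alone separates the groups on a given component in 10% of cases, so the second cannot be read as an effect of RiNLE1. With EV replicate 1 and RiNLE1 replicate 1 both left out, a setting chosen after seeing the data, edgeR called 2 genes, 1 higher and 1 lower.

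**Figure D4:**
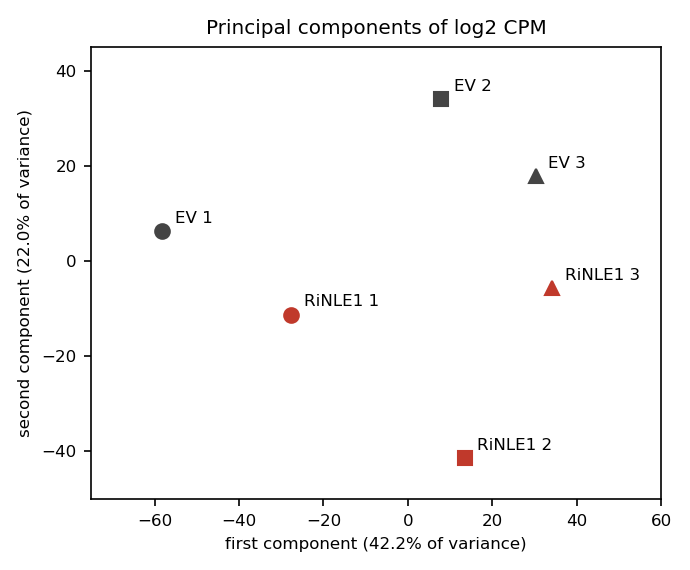
First and second principal components of log2 CPM over the 21100 tested genes, with 1 point per library (grey for EV, red for RiNLE1, shape for the replicate number). EV replicate 1 and RiNLE1 replicate 1 lie at the low end of the first component. The groups lie on opposite sides of 0 on the second, which can arise by chance.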

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

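The likelihood ratio, exact, surrogate variable, non-robust and DESeq2 leave-one-out fits, the corrected lists, and the fits without EV 1 and RiNLE1 1 were chosen after seeing the data. The quasi-likelihood count of 0 genes held under every scaling and filter, limma-voom, 1 surrogate variable, no robust estimation, and each library left out. DESeq2 called 41 genes (32 changed at least 2-fold), the likelihood ratio test 35 (31), the exact test 33 (29), and edgeR without EV 1 and RiNLE1 1 called 2 (2); in simulations with no changed gene DESeq2 called 23 to 34 and edgeR 0 to 2, and for the likelihood ratio and exact tests the cause was not tested. With 1 library left out, the counts of genes ranged from 0 (edgeR, each fit) to 159 (DESeq2 without RiNLE1 replicate 1), and those at least 2-fold from 0 to 111. DESeq2 called 96 (57 at least 2-fold), 12 (11) and 52 (39) without EV replicates 1, 2 and 3, and 159 (111), 19 (17) and 15 (15) without RiNLE1 replicates 1, 2 and 3. Of the 41 genes, between 8 and 32 were called again in each such DESeq2 fit. For lists, camera with an estimated correlation and fry called 0 in place of 6, the corrected words 7, genes with a mean of at least 5 CPM 8, and fits with 1 library left out between 2 (without RiNLE1 replicate 3) and 13 (without EV replicate 2). Same-number correlations of deviations from the group means were 0.454, -0.0918 and 0.228, which leaves open whether the replicate numbers pair the libraries. With the replicate block, edgeR called 0 genes (0 at least 2-fold) and camera 8 lists, among them UDP-glycosyltransferases (adjusted p = 0.0159) and sugar transporters (0.0217). Of the values of the named genes under alternatives, 589 kept their direction and stayed short of the threshold, 22 passed it with DESeq2, and 4 reversed. These counts leave out the likelihood ratio, exact, surrogate variable, non-robust and DESeq2 leave-one-out fits. Some of the 22 were named because DESeq2 called them. Medtr1g040500 gave 0.013 with limma-voom, 0.45 without EV 1 and RiNLE1 1, and between -2.14 and 1.89 with 1 library left out; Medtr4g132367 gave -0.0849 without RiNLE1 replicate 3 and up to 0.47 in such fits. The median of all genes ran from -0.0132 to -0.00419 across scalings, and the corrected H2B list, which takes in genes described as core histone H2A/H2B, changed sign around a median of 0.00. At 17628994 to 18548414 counts per library, genes with low expression rest on few reads, which limits what can be called among them.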

Other observations

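No other list was called by camera in the planned test, though some were in alternatives. Sugar transporters had an adjusted p of 0.0349 with corrected words, and cytokinin genes 0.037 and leghemoglobin and nodulin genes 0.0223 among genes with a mean of at least 5 CPM. In a list of 32 histone genes other than H2B, with a median log2 fold change of 0.02, 3 were higher at an unadjusted p under 0.05 and 0 lower; camera called the list only without EV replicate 3 (adjusted p = 0.000319). These 3 were linker histones, such as Medtr1g070435 at 71.7 ± 6.01 CPM in EV and 93.5 ± 4.27 CPM in RiNLE1 (SD, n = 3). Aquaporins had 28 tested genes with the patterns corrected after the descriptions were seen, and 3 lower at an unadjusted p under 0.05. One of them, Medtr2g017570, passed when adjusted over the list alone (edgeR adjusted p = 0.0236) at 1.45 ± 0.118 and 0.364 ± 0.131 CPM. The list's median was 0.08 and its mean -0.02. As first fixed the list held 7 tested genes, with a median of -0.04 and 0 calls when adjusted over the list alone (lowest edgeR adjusted p = 0.752). The early nodulin Medtr4g113820 was called by DESeq2 at 26.0 ± 6.14 CPM in EV and 75.2 ± 33.0 CPM in RiNLE1, and so was the dehydrin Medtr3g117290 at 386 ± 12.9 and 541 ± 28.6 CPM. The reductase Medtr8g072640, of the early isoprenoid pathway, was also called by DESeq2, at 513 ± 51.0 and 788 ± 92.6 CPM. Of the 6 DESeq2 fits with 1 library left out, the early nodulin was called again in 3, and the dehydrin and the reductase in 2 each. Phenylpropanoid genes had 6 members higher and 0 lower at an unadjusted p under 0.05 among 146, with a median of -0.02 and a camera call only without EV replicate 2 (adjusted p = 0.00737), and auxin genes 4 higher and 4 lower among 149.

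Several genes called by DESeq2 rested on a part of the RiNLE1 libraries. The 3 given here were left out by edgeR's filter, because too few libraries held enough counts, and were not tested by it. Medtr7g024880, a calcium-binding EF-hand protein, had 5, 2 and 9 counts in EV and 7, 180 and 81 in RiNLE1. Medtr4g428370, a lipid transfer protein, had 3, 3 and 4 counts in EV and 2, 41 and 173 in RiNLE1. Medtr1g056370, a disease resistance response protein, had 2, 1 and 2 counts in EV and 1, 108 and 58 in RiNLE1. In each case RiNLE1 replicate 1, the library with the most effector reads (2705 CPM), stayed at the EV level.

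All tests of explanations given from here on were chosen after the results were seen. The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The quasi-likelihood test gave 0 genes in the real split and at most 3 in another (2 changed at least 2-fold), so that 10 of 10 splits gave a count as large, which a count of 0 fixes beforehand and which says nothing about chance. camera called 6 lists in the real split and up to 23 in another, with 6 of 10 splits as large. For each of the 6 lists (jasmonate with corrected words) another split gave a larger absolute median log2 fold change. It reached 0.498 for protease inhibitors, against 0.364 in the real split, and 0.218 for receptor-like kinases, against -0.115.

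DESeq2 called 41 genes in the real split and up to 520 in another, and 5 of the 10 splits gave as many. The 4 splits with EV replicate 1 and RiNLE1 replicate 1 in one group gave 335, 51, 520 and 39 calls; the largest of these point to a structure of the samples, though not all 4 exceed the real count. In 5 simulations with no changed gene, DESeq2 called up to 34 genes, over the 21100 genes that edgeR tested, where 37 of the real calls lay, though these came from a fit over more genes, so false calls may account for many of these but were not shown to account for all. Of the 41, 7 genes were called in every fit with 1 library left out, where another split gave up to 188 such genes. Chance, false calls and an effect of RiNLE1 stay open for these genes.

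EV replicate 1 and RiNLE1 replicate 1 lay together on the first principal component. An exchange of libraries between the groups is argued against by the effector reads, since the highest EV library held 0.325% of the lowest RiNLE1 library, although this entry was read as the effector partly because of that contrast. Library size is argued against too, because 1 other library (RiNLE1 replicate 2) had a total between theirs, and the largest total was 1.05 times the smallest. Handling of same-numbered roots together was examined by same-number correlations of deviations from the group means, at 0.454, -0.0918 and 0.228 for numbers 1, 2 and 3. In groups of 3 libraries these deviations constrain each other, so the correlations cannot exclude such handling, which stays open. No biological explanation was tested, since the design names none that these libraries share.

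The 8 tested Bet v I genes on chromosome 8 had a median log2 fold change of 0.87, and the largest absolute median of another split was 0.456. That 1 of 10 splits, the real one, was as large says nothing against chance, because the stretch was chosen for its values in this split. The estimate did not hang on a single library, since the lowest median with 1 library left out was 0.72. Without both EV 1 and RiNLE1 1 the median was 0.71, with all 8 genes above 0. Choosing the stretch for its values makes such stability likelier, so it is no evidence of an effect of RiNLE1. Chance, reads shared between copies and an effect of RiNLE1 stay open. Over all 17 tested genes with the Bet v I description the median was 0.35, where another split reached 0.332. Genes described otherwise, such as the lower allergen Pru and ABA-responsive genes, were not counted among these 17.

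One hypothesis was that the effector acts through ubiquitination of histone H2B, a mark of transcribed genes tied to elongation, so that longer genes may be lower in RiNLE1. Across the 21100 genes, which are not independent replicates, the rank correlation of gene span and log2 fold change was -0.0245, and in the other 9 splits it ran from -0.199 to 0.0383. The data therefore did not bear out a shift with gene length beyond that of other splits. Because those splits spread so widely, the comparison could not detect a smaller shift, and the hypothesis stays open.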
